A study of Canis lupus familiaris with 5 samples.

How the data were processed

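Expression was measured in 5 samples of canine myocardium, each hybridised to its own array, and grouped by the condition in the sample titles into 2 control and 3 failing samples. The table deposited by the authors gives 1 linear intensity per probe set and array. No protocol, scanner software, array control procedure or normalization is given in the sources used here. The deposited intensities themselves show a common scale, since the mean of every array after removal of the lowest and highest 2% of probe sets is 800. They are negative for 34.7% to 39.9% of probe sets per array, as a difference between matching and mismatching probes would be, and such a difference has no logarithm below 0. The annotation pairs probe sets with human genes, while the RNA was from dog. Sequence differences between the species could lower the signal of matching probes, raise that of mismatching ones or move signal between related genes, by an amount that would differ between probe sets and be shared by the arrays.

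Of 4653 probe sets, 52 are array controls and were left out of all tests. Of the 4601 others, 3724 had 1 gene symbol, 72 several and 805 none. Genes were named only from probe sets with 1 symbol, as given in the platform annotation, and list members under older symbols were matched to it. Columns of other samples numbered 0. No genome build belongs to the table, so no coordinates are given. No scaling was added, because the trimmed means of the arrays agreed. Intensities were raised to a floor of 20 and put on the log2 scale, so fold changes of dim genes depend on the floor, and no fold is given for a gene with any array below it, where a log2 fold change is given only as a value on floored data. Probe sets were tested when their mean log2 intensity over the 5 arrays was at or above the median, 7.13 (an intensity of 140.1). A gene with several such probe sets was represented by the one with the highest mean. This left 1449 genes and 2301 probe sets.

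Failing and control samples were compared per gene in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with an intensity trend), two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Errors of log2 fold changes are standard errors of that fit and errors of intensities are SDs over the 2 control or 3 failing arrays. A gene was called separated when all failing values lay above or all below both control values, which chance gives in 10% of genes in each direction if the 5 arrays are independent. The 3′ to 5′ ratios of array control probe sets were compared by exact permutation tests. Such a two-sided exact permutation test cannot go below 0.2 with 2 against 3 arrays.

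Gene lists were tested with camera at a preset correlation of 0.01, which compares a list with all other tested genes, beside camera with an estimated correlation and fry, which asks whether the members themselves move in a common direction. Of 27 lists, 19 had at least 5 tested members and 8 did not. With an estimated correlation, camera takes its degrees of freedom from the arrays rather than the genes, and 5 arrays leave few. The p-values were adjusted over the 19 lists, and members also over each list alone. The lists cover the cardiac stress and fetal program, calcium handling, sarcomere, ion channels, fatty acid, oxidative phosphorylation, tricarboxylic acid cycle, glucose, creatine kinase, extracellular matrix, matrix protease, TGF-beta, adrenergic signaling, chaperone, ribosomal protein, proteasome, complement and immediate early genes, and markers of 9 other cell types or tissues.

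The groups, tests, lists and the rule for named genes were fixed before the data were examined. That rule took up to 15 genes per direction with the largest change among those past the threshold and separated, filled up with the separated genes of smallest p to 10 per direction where fewer passed, and stated as not passing. It added 25 genes of heart failure studies whatever their values, of which 17 were on the array and 15 were tested, and up to 4 members per list with the largest moderated statistic. It took 109 genes in all, of which a part is described. Of the 25, SLC8A1, KCND3, KCNJ2, TIMP1, ADRB1 and GRK5 were not analysed here, as NPPA and NPPB.

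Before use, the tests were run on simulated data with 200 changed genes in each of 20 sets of 1449 genes. In this simulated failing against control comparison, 10.3% of genes changed by a log2 of 1 were recovered, 36.8% of those changed by 2, 56.2% by 3 and 66.1% by 4, and 4.83% of calls were false. A shift of −0.5 seeded in the oxidative phosphorylation list was called in 100% of sets with the preset correlation and in 35% with the estimated one. At the preset correlation 0 other lists were called, in a count that left out the tricarboxylic acid cycle list. The simulated values were drawn independently for each gene and array, with no correlation between genes, no floor and no shared pools. These rates therefore need not hold for the deposited data.

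Alternatives were quantile normalization, division by the 75th percentile, no filter on dim probe sets, only the rows above the 75th percentile of brightness, floors of 1 and 100, no intensity trend, robust moderation, the number in the sample titles as a block, failing 1a and 1b averaged, each array left out in turn, the mean of a gene's probe sets, probe sets in place of genes, and an estimated correlation. A floor of 400 and a filter at a mean intensity of 800 were added after the data had been seen. Robust moderation does not apply to camera and was not run for lists.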

Results

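Transcript levels were measured in canine heart muscle, described only as myocardium, from control dogs and from dogs in congestive heart failure. The set held 5 oligonucleotide arrays, 2 from control myocardium (control 1a and 2a) and 3 from failing myocardium (failing 1a, 1b and 2a). On 4 of the arrays the RNA of 3 dogs had been pooled before labelling, and the pool behind control 1a was not described. Whether failing 1a and 1b were separate pools or repeat arrays of the same pool was not stated, so p-values measure only the spread between these arrays, which may be technical. How heart failure arose was not given in the sources used here. Values were linear intensities, scaled so that the trimmed mean of every array was 800, and 34.7% to 39.9% of the probe sets of an array lay below 0. The table held 4653 probe sets, of which 3724 were paired with 1 gene symbol, giving 2416 genes. The 1449 genes bright enough to be tested form the basis of all comparisons, and the number of arrays limits their precision.

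The arrays of failing 1a and 1b were closest to each other (r = 0.820 across genes, median absolute log2 difference 0.31), followed by the 2 control arrays (r = 0.790, difference 0.41). Failing 2a stood apart from all other arrays, with r between 0.561 and 0.581 and a median absolute difference between 0.81 and 0.89. These correlations run across genes, which are not independent replicates. No pair of arrays held identical values.

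The comparison of failing with control myocardium asks which transcripts differ in the failing heart. Genes of oxidative phosphorylation and of the cytosolic ribosome fell as groups in failing myocardium relative to the other genes tested, in camera with a preset correlation. Both calls were lost with an estimated correlation (adjusted p = 0.255 and 0.364 with an estimated correlation), and neither list passed in fry (adjusted p = 0.269 and 0.276). Their median log2 fold changes were −0.32 and −0.23, or −0.48 and −0.39 relative to the median of all genes. Among single genes, only CST3, which encodes the secreted protease inhibitor cystatin C, passed the adjusted threshold, with opposite directions at its 2 probe sets. The connective tissue growth factor gene CCN2 and the Z-disc gene ACTN2 were brighter on every failing array, on average by 3.16-fold and 3.52-fold, without passing it. Several genes of the extracellular matrix and of the endothelium also lay above control on all 3 failing arrays, and neither list passed in camera.

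Across the 1449 genes, limma with Benjamini-Hochberg adjustment called 1 gene higher and 0 lower in failing myocardium. At an unadjusted p under 0.05 there were 152 genes, 100 higher and 52 lower, where chance gives 72.45. That split depended on the scaling of the arrays and on the filter. It was 65.8% higher with the deposited scale, 58.6% after quantile normalization and 45.5% (60 higher, 72 lower) when each array was divided by its 75th percentile. The median log2 fold change of all genes moved with it, from 0.15 to −0.00087 and −0.05. Without the filter on dim probe sets 60.4% were higher (128 higher, 84 lower) and the median was 0.05. In 454 genes (31.3%, where chance gives 20%) the values of the groups did not overlap, 283 higher and 171 lower. These chance shares, and those given for each list, hold for 5 independent arrays. If failing 1a and 1b are repeats of the same pool, chance gives 33.3%, and with those arrays averaged 584 genes (40.3%) were separated, 359 higher and 225 lower. Separation upward was thus more common than chance among all tested genes, and the counts of each list are to be read against these totals too. The filter used the mean of 3 failing and 2 control arrays, so it kept genes bright in failing myocardium more readily. Of the tested genes, 14 were below the floor on all control arrays and 0 on all failing arrays. The count of called genes was 12 without failing 2a, 3 without control 2a, and 0 without failing 1a or without failing 1b, whose counts at an unadjusted p under 0.05 were 108 and 100. Without failing 2a the count at an unadjusted p under 0.05 was 234, but that fit leaves only failing 1a and 1b, possibly repeats of the same pool.

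The oxidative phosphorylation list covers subunits of the respiratory chain and of ATP synthase. Of its 52 tested members, 34 had a log2 fold change below 0, and 21 lay below control on every failing array against 6 above, where chance gives 5.2 in each direction (21 and 8 with failing 1a and 1b averaged, where chance gives 8.67). The list fell relative to the other genes in camera (adjusted p = 0.000173 over 19 lists). The call was lost with an estimated correlation between genes (adjusted p = 0.255 with an estimated correlation), and fry gave p = 0.0283 (adjusted p = 0.269). The estimated correlation was −0.014, below the preset 0.01, so correlation between its genes was not what undid the call. With an estimated correlation, camera takes its degrees of freedom from the arrays, and 5 arrays leave few (unadjusted p = 0.0134). In the simulated sets, without correlation between genes, that version called a shift of −0.5 in only 35%. The loss of the call therefore says little for or against a shift. At an unadjusted p under 0.05, 12 members were lower and 2 higher. No member passed the threshold over all genes. Adjusted over the list alone, 1 member passed and it was higher, ATP5F1D, a subunit of the ATP synthase stalk (log2 fold change 7.78 ± 0.79 SE on floored values, adjusted p over all genes = 0.0713). Both control arrays were below the floor, so its size is set by the floor and no fold is given. Its intensities were −12429 and −21313 on the control arrays and 4312, 2048 and 9624 on the failing arrays. The list's mean log2 fold change was −0.10, nearer 0 than its median. ATP5F1D counts in this mean and in the means per array, and raises them on all failing arrays by an amount set by the floor. Per array, relative to the control mean, the mean over members was 0.02 on failing 1a and 0.02 on failing 1b, inside the range of the control arrays (−0.06 to 0.06), and −0.33 on failing 2a. For the median over members, failing 1a, 1b and 2a lay at −0.36, −0.16 and −0.57, below both control arrays. Within the list the median was −0.33 over 23 genes of complex I, −0.59 over 4 of complex III, −0.42 over 12 of complex IV and −0.23 over 12 of ATP synthase. The 1 tested gene of complex II had 0.05.

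Among single members, the ATP synthase c-ring gene ATP5MC1 had an intensity of 85110 ± 6543 (SD) on the control arrays and 50858 ± 5502 on the failing arrays, a log2 fold change of −0.75 ± 0.16 (SE, adjusted p = 0.291). Its other probe set went the same way, with a mean of 33332 in control and 17827 in failing myocardium. COX7A1, the muscle isoform of a cytochrome c oxidase subunit, had −0.96 ± 0.21, and CYC1, cytochrome c1 of complex III, −0.91 ± 0.22. Both lay below control on all failing arrays, with adjusted p of 0.294 and 0.299. CHCHD10, a mitochondrial intermembrane space protein outside the list, had −1.03 ± 0.20 (adjusted p = 0.267), from 68770 ± 1761 to 33989 ± 6244.

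The cytosolic ribosomal protein list had 57 tested members, of which 42 lay below 0. On every failing array 23 members lay below control and 2 above, where chance gives 5.7 in each direction (27 and 3 with failing 1a and 1b averaged, where chance gives 9.5). The list fell in camera (adjusted p = 1.85e-05). This call too was lost with an estimated correlation (adjusted p = 0.364 with an estimated correlation), and fry gave p = 0.0487 (adjusted p = 0.276). Here the estimated correlation was 0.037, above the preset 0.01, and camera with it gave an unadjusted p of 0.0383. The few degrees of freedom of 5 arrays weighed on this test as well, so correlation alone need not account for the loss. Adjusted over the list alone, RPLP2 was the member that passed, and over all genes it did not (adjusted p = 0.0713). RPLP2 encodes an acidic stalk protein of the large subunit. It had a log2 fold change of −1.72 ± 0.21 (SE), 0.303-fold, from 31515 ± 2870 (SD) to 9625 ± 1596. Its other probe set went from 1493 to 592. RPL37 had −1.18 ± 0.22 (adjusted p = 0.244), RPL12 −0.75 ± 0.24 and RPS9 0.77 ± 0.23, the last with a second probe set in the opposite direction. The second probe set of RPL12 hardly changed, from 4607 to 4458 (log2 difference −0.06). Ribosomal protein genes have many near-identical processed pseudogenes, so single members are uncertain where a probe set could also detect such copies.

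**Figure D1:**
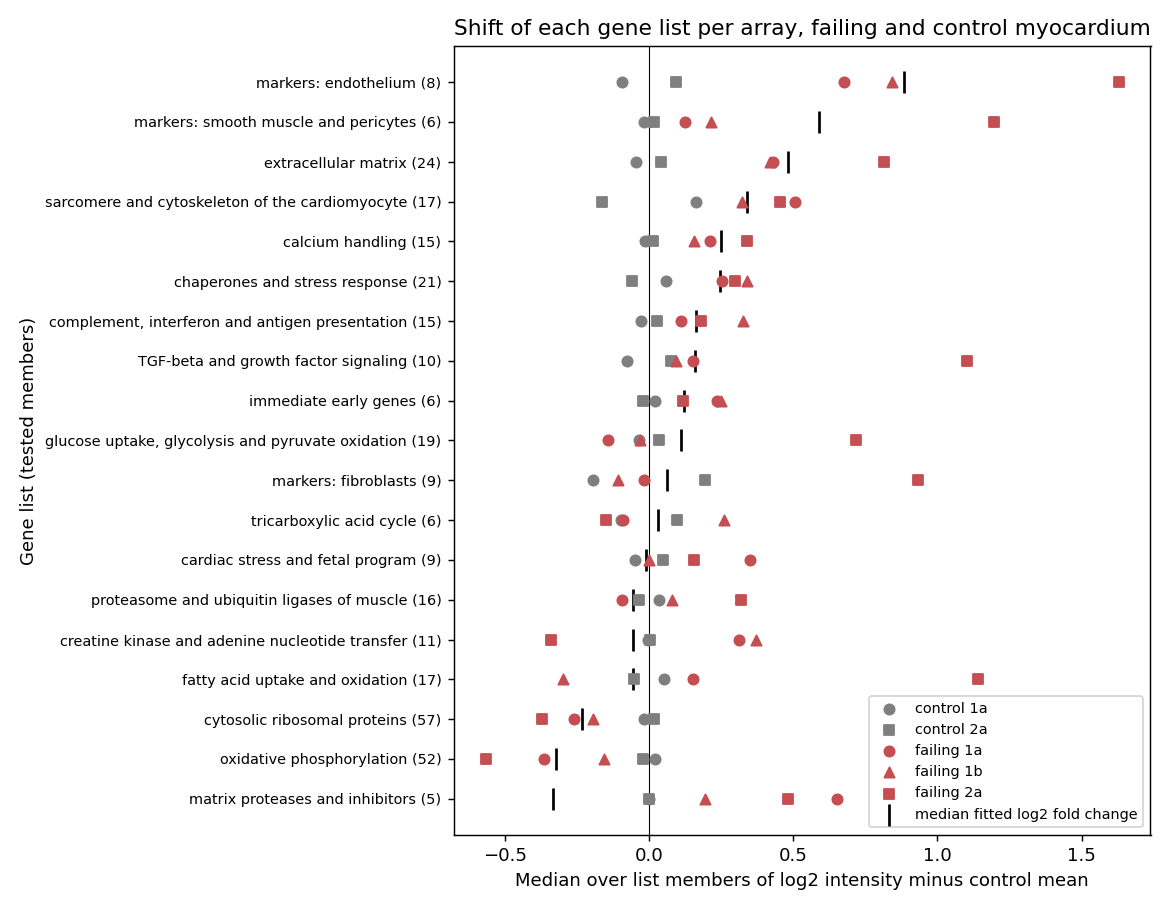
Each row is a gene list with its number of tested members, and the horizontal axis gives, for each array, the median over members of log2 intensity minus the control mean; grey marks are control arrays, red marks failing arrays, and the black bar is the median fitted log2 fold change of the members. The failing arrays lie below both control arrays for oxidative phosphorylation (median −0.32) and cytosolic ribosomal proteins (−0.23), and above them for the endothelial (0.88) and extracellular matrix (0.48) lists, which did not pass their test.

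Array controls also differed between the groups. The ratio of the 3′ to the 5′ probe set of GAPDH was 2.24 ± 0.13 (SD) on the control arrays and 1.39 ± 0.06 on the failing arrays. The same ratio for actin was 0.0992 ± 0.013 and 0.162 ± 0.065. Its mean thus went the other way, and the groups overlapped, with 0.087 on failing 1b against 0.090 and 0.108 on the control arrays. The mean log2 intensity of 9 bacterial control probe sets was 14.21 ± 0.06 and 13.21 ± 0.67, 0.501-fold, and 6 of the 9 were lower on every failing array. Two-sided exact permutation tests gave p = 0.2, 0.6 and 0.2, and 0.2 is the smallest p that 2 arrays against 3 can give. The control arrays, with the higher GAPDH ratio, also had the higher medians of the oxidative phosphorylation and ribosomal lists and the lower medians of the matrix and endothelial lists. For the means of the oxidative phosphorylation and ribosomal lists the groups overlapped, with ribosomal means of −0.092 on control 1a and −0.091 on failing 1b. The oxidative phosphorylation means of the failing arrays were raised by ATP5F1D, whose control values were floored.

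The extracellular matrix list had 24 tested members with a median log2 fold change of 0.48, or 0.33 relative to all genes. On every failing array 10 members lay above control and 0 below, where chance gives 2.4 in each direction (11 and 4 with failing 1a and 1b averaged, where chance gives 4). Over all 1449 genes the counts were 283 above and 171 below (359 and 225 averaged), so part of the excess above control was shared by all genes. The list did not pass in camera, with an adjusted p of 0.237. It did not pass in fry for a common direction, with an adjusted p of 0.146. Fry's mixed test, which asks for change in either direction, gave an adjusted p of 0.000751. That test passed for 8 of the 19 lists, among them oxidative phosphorylation (0.0403), sarcomere (0.0326), TGF-beta (0.0246) and proteasome (0.0246), so a pass is not particular to the matrix list. Adjusted over the list alone, COL3A1 passed. COL3A1 encodes the chain of type III collagen and had a log2 fold change of 2.36 ± 0.43 (SE, adjusted p over all genes = 0.244), 5.13-fold, from 298.9 ± 93.6 (SD) to 1499 ± 136. SPARC, a collagen-binding matricellular protein, had 0.78 ± 0.20 (adjusted p = 0.301), the fibrillar collagen gene COL1A2 1.28 ± 0.51, and the matrix protein gene PRELP 0.77 ± 0.26. COL1A1 had 0.50 ± 0.71 with overlapping groups. Fibronectin, FN1, had an intensity of −57.8 ± 199 in control and 493.4 ± 304 in failing myocardium. The direction of the list held after quantile normalization and after 75th percentile scaling.

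The fibroblast marker list shares collagen genes with the matrix list and had a median of 0.06 over 9 members, which was below 0 under both other scalings (camera adjusted p = 0.867, fry mixed adjusted p = 0.00196), and COL3A1 again passed over that list alone. The median of matrix proteases and inhibitors was −0.33 over 5 members while their mean was 0.17, with camera pointing down, fry pointing up and a camera adjusted p of 0.996. In that list TIMP3, an inhibitor of matrix metalloproteinases, had control intensities of −2645 and −3618 against 2732, 88.3 and 2192 in failing myocardium.

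All 8 tested endothelial markers had a log2 fold change above 0, with a median of 0.88 (camera p = 0.0411, adjusted p = 0.237, and adjusted p = 0.886 with an estimated correlation). On every failing array 4 of them lay above control, against 0.8 by chance (5 with failing 1a and 1b averaged, against 1.33). Of all 1449 genes, 283 lay above control (359 averaged), which is also more than chance gives. The water channel gene AQP1 had 1.72 ± 0.66 (SE), CDH5, the endothelial cadherin, 2.40 ± 1.09 with a dim second probe set in the opposite direction, and von Willebrand factor, VWF, 0.86 ± 0.41, with adjusted p between 0.457 and 0.532. The smooth muscle and pericyte markers had a median of 0.59 over 6 members (camera adjusted p = 0.867). In that list LMOD1 had 0.95 ± 0.39 and TAGLN, the smooth muscle protein transgelin, −1.01 ± 0.34.

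Growth factor and stress genes went both ways. CCN2 lay above control on each failing array, going from 4036 ± 192 (SD) to 12793 ± 1619, a log2 fold change of 1.66 ± 0.19 (SE). Its adjusted p was 0.0713 over all genes, and it passed when adjusted over the TGF-beta list alone and over the cardiac stress and fetal program list alone. Without failing 2a its adjusted p was 0.0357, in a range from 0.0357 to 0.427 over its alternatives. The fit without failing 2a leaves only failing 1a and 1b, which may be repeats of the same pool, so its p may rest on technical spread. The TGF-beta and growth factor list had a median of 0.16 over 10 members, which turned to −0.04 under both other scalings (camera adjusted p = 0.917). In it VEGFA had 1.65 ± 0.78 and IGFBP4 −1.08 ± 0.52, each with a second probe set in the opposite direction. The cardiac stress and fetal program list had a median of −0.01 and a mean of 0.09 over 9 members (camera adjusted p = 0.996, direction down, fry up with an adjusted p of 0.276, fry mixed adjusted p = 0.00104). Its alpha myosin heavy chain, MYH6, a fast myosin isoform of heart muscle, had −0.54 ± 0.18 (adjusted p = 0.418), from 49947 ± 343 to 34504 ± 4801. Skeletal alpha-actin, ACTA1, which is expressed in the fetal heart, had 0.78 ± 0.30 (adjusted p = 0.457). Beta myosin heavy chain, MYH7, and the angiotensin receptor AGTR1 were too dim to be tested, and NPPA and NPPB, which encode the natriuretic peptides, were not analysed here. The MYH7 probe sets had control means of −564 and −3423. Human probe sets of MYH6 and MYH7 may not tell these related transcripts apart in dog RNA, so low MYH7 readings need not mean low expression.

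In the sarcomere and cytoskeleton list, with 17 tested members, a median of 0.34 and a camera adjusted p of 0.867, 6 members lay above control on every failing array and 3 below. Adjusted over the list alone, ACTN2 and PDLIM5 passed, and both encode Z-disc proteins. ACTN2, alpha-actinin 2, had 1.81 ± 0.28 (SE, adjusted p over all genes = 0.173), from 2701 ± 537 (SD) to 9581 ± 2162. Without failing 2a its adjusted p was 0.0427, in a range from 0.0427 to 0.666 over its alternatives. That fit leaves only failing 1a and 1b, which may be repeats of the same pool. PDLIM5 had 1.21 ± 0.22 (adjusted p = 0.244), 2.32-fold, and both its other probe sets went the same way. However, 1 of them was below the floor on both control arrays and on 2 failing arrays, so its direction rests on a single array. The titin cap gene TCAP had 0.80 ± 0.23, with 1 of its 3 other probe sets in the same direction. Zyxin, ZYX, a focal adhesion protein outside the list, had 1.37 ± 0.21 (adjusted p = 0.173), 2.58-fold.

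The calcium handling list, with 15 tested members, had a median of 0.25 and a mean of 0.35, with camera pointing down and fry up (camera adjusted p = 0.996). ATP2A2, the calcium pump of the sarcoplasmic reticulum, had 1.35 ± 0.79 (SE), and 1 of its 2 other probe sets went the opposite way. Phospholamban, PLN, had 0.63 ± 0.90, the ryanodine receptor RYR2 0.66 ± 0.60 and calsequestrin, CASQ2, 0.75 ± 0.54. The calcium-binding protein S100A1 had −0.82 ± 0.30 and triadin, TRDN, −0.46 ± 0.20. The adjusted p of these genes lay between 0.442 and 0.830. The gap junction gene GJA1 had −0.29 ± 0.37 and the sodium pump subunit ATP1B1 0.64 ± 0.73. They were the 2 tested members of the ion channel list, too few for a list test.

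The lists of fuel use did not pass. Fatty acid uptake and oxidation had a median of −0.06 over 17 members (camera down, fry up, camera adjusted p = 0.917). In it ETFB, a subunit of the electron transfer flavoprotein, had 1.32 ± 0.28 (SE, adjusted p = 0.291) with a second probe set in the opposite direction. The fatty acid binding protein gene FABP3 had −0.46 ± 0.26, and its second probe set 0.06. HADHA, a subunit of the mitochondrial trifunctional protein, lay below control on every failing array, with intensities of 1048 ± 1050 (SD) in control and −266.3 ± 518 in failing myocardium (adjusted p = 0.508). CPT1B, the muscle carnitine palmitoyltransferase, had a control intensity of 100.7 ± 266 and a failing intensity of 1060 ± 502. The list of glucose uptake, glycolysis and pyruvate oxidation had a median of 0.11 over 19 members, which was −0.09 with 75th percentile scaling, with camera down and fry up (camera adjusted p = 0.996). The glycolytic enzyme genes ENO1 and ALDOA were at 2.83-fold (log2 SE 0.49) and 2.22-fold (log2 SE 0.48) of control, with adjusted p of 0.418 and 0.473. PDK4, which inhibits pyruvate dehydrogenase, had a log2 fold change of 1.17 ± 0.87 and the glucose transporter SLC2A4 0.18 ± 0.36. The tricarboxylic acid cycle list had a median of 0.03 and a mean of −0.34 over 6 members, with a camera adjusted p of 0.867 and a negative median under both other scalings. In it OGDH, a subunit of the oxoglutarate dehydrogenase complex, had −0.90 ± 0.39. The creatine kinase and adenine nucleotide list had a median of −0.06 and a mean of 0.14 over 11 members, camera and fry pointing up (camera adjusted p = 0.996). Adjusted over that list alone, AMPD1, the muscle AMP deaminase, passed, with a log2 fold change of 5.03 ± 0.93 on floored values and failing intensities of 1687 ± 139. The muscle creatine kinase gene CKM had 0.16 ± 0.32, with another probe set from 3641 to −838.

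Chaperone and stress response genes had a median of 0.24 over 21 members, with 9 above control on every failing array and 3 below (camera adjusted p = 0.867, fry mixed adjusted p = 0.0246). The small heat shock protein genes HSPB2 and HSPB7 had 0.63 ± 0.20 (SE) and 1.04 ± 0.36, and the transcription factor gene ATF4 0.81 ± 0.27. The proteasome and ubiquitin ligase list had a median of −0.05 and a mean of 0.37 over 16 members, with camera down and fry up (camera adjusted p = 0.996). In it TRIM63, a ubiquitin ligase of muscle, had control intensities of −606 and −306.8 and failing intensities of 627.7, 310.9 and 1384. PSMD11, of the proteasome's regulatory particle, had 1.18 ± 0.39 with a dim second probe set in the opposite direction. The complement, interferon and antigen presentation list had a median of 0.16, which was below 0 under both other scalings, and a mean of −0.19 over 15 members, with camera down and fry up (camera adjusted p = 0.917). The class I genes HLA-B and HLA-C had −0.78 ± 0.27 and 0.60 ± 0.27, and probe sets of such closely related genes may not tell them apart. The immediate early gene list had a median of 0.12 over 6 members, which was below 0 with 75th percentile scaling (camera adjusted p = 0.917).

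Markers of other cell types had too few tested members for a list test. Among myeloid markers, TYROBP had 0.22 ± 0.29 (SE) and S100A9 −0.03 ± 1.42. LAPTM5, with 1 control array below the floor, had intensities of 112.8 ± 216 (SD) in control and 689 ± 483 in failing myocardium. The lymphocyte marker CD52 had 2.63 ± 1.38 with another probe set in the opposite direction. Of the blood markers, HBB had 0.94 ± 0.37, with another probe set in the opposite direction (from 1068 to 882.2), and HBA1 −0.05 ± 0.42. Of the adipocyte markers, PLIN1 had −0.34 ± 0.28, CFD −0.13 ± 0.18 with another probe set in the opposite direction, and LIPE 0.33 ± 2.01. LPL read below the floor on 1 array of each group, with intensities of −360.6 ± 1642 and 1214 ± 2505. The nerve and Schwann cell marker MBP had 1.57 ± 0.86, and the atrial markers SLN and PAM had −0.54 ± 0.55 and −0.75 ± 0.42. In the adrenergic, renin-angiotensin and endothelin list, GNAS had 0.92 ± 0.39, NPR1 0.70 ± 0.54, PRKAR1A 0.27 ± 1.03 and PRKACA 0.16 ± 0.65. The smallest adjusted p among these genes was 0.464.

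CST3 had a log2 fold change of 8.41 ± 0.47 (SE, adjusted p = 0.00622) on floored values, so that no fold can be given. Its tested probe set read −3579 and −4169 on the control arrays and 7543, 4991 and 8347 on the failing arrays. The other CST3 probe set went the opposite way, with a mean of 1853 in control and 592.9 in failing myocardium. Under quantile normalization and with a floor of 1 that probe set was the brighter, and the log2 fold change was −2.63 and −4.36. The call was lost with failing 1a and 1b averaged (adjusted p = 0.185), without failing 1a (0.307) and without failing 1b (0.145), while the log2 fold change stayed at 8.48, 8.33 and 8.63. With the mean of its probe sets it was lost at a log2 fold change of 2.74 (adjusted p = 0.505). RNASEK, CHRNB1 and PER1 likewise read below 0 on both control arrays, and had adjusted p of 0.0713, 0.092 and 0.244.

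Of the named genes, 60 had further probe sets. Of these 85 probe sets, 37 went in the direction of the tested one, 29 in the opposite direction, and 19 were below the floor on all arrays. Among the 39 bright enough to be tested, 24 went the same way and 15 the opposite way. COL1A1, HSPB2, LPL, PRELP, S100A1, TRDN and TYROBP also had opposite probe sets too dim to be tested. The genes lower in failing myocardium by the smallest p, none of which passed, also included the glutathione transferase gene MGST3 (−1.03 ± 0.21 SE), the thioredoxin-binding protein gene TXNIP (−1.02 ± 0.22), the stress-inducible gene GADD45A (−0.99 ± 0.23), ERP29 and the RNA polymerase subunit gene POLR2H (−2.11 ± 0.46). Both other probe sets of POLR2H went the opposite way. Their adjusted p lay between 0.291 and 0.299.

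**Figure D2:**
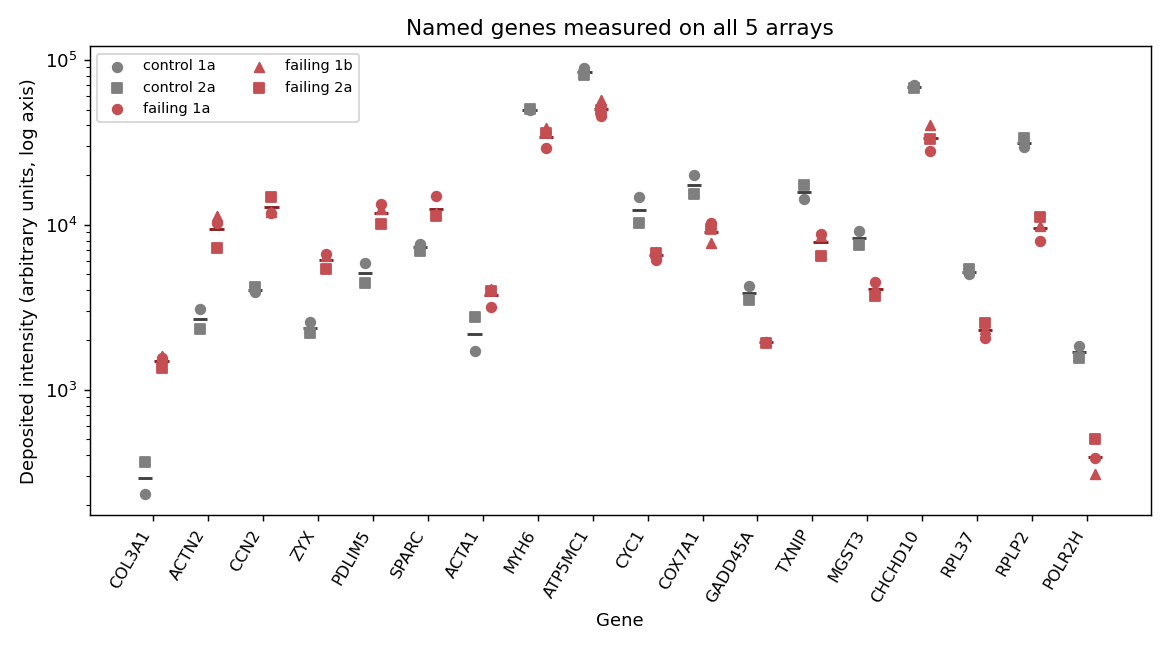
Deposited intensity (vertical axis, arbitrary units, log scale) of 18 named genes with values above the floor on all 5 arrays; grey marks are control arrays, red marks failing arrays, and short bars are the means of the log2 values. COL3A1 goes from 298.9 to 1499 and RPLP2 from 31515 to 9625, and no gene shown passed the adjusted threshold over all genes.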

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

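The floor of 400 and the filter at a mean intensity of 800 were chosen after seeing the data, and each again called 1 gene, CST3, and the same 2 lists. The number of called genes was 0 with quantile normalization, a filter at the 75th percentile of brightness, a floor of 1, failing 1a and 1b averaged and the mean of probe sets, where the counts at an unadjusted p under 0.05 were 133, 107, 140, 98 and 131. It was 2 with 75th percentile scaling (CST3, ATP5F1D) and 2 when probe sets were counted, 3 without the intensity trend, and 5 without the filter, 4 of them lower. With an array left out the number called ranged from 0 to 12, with 0 to 7 higher and 0 to 5 lower, and the number at an unadjusted p under 0.05 from 96 to 234, against 152. The 12 genes came without failing 2a and included CCN2, ACTN2, RPLP2 and ATP5F1D. That fit leaves only failing 1a and 1b as failing arrays, which may be repeats of the same pool. Its p-values may thus rest on technical spread, and with those arrays averaged 0 genes were called. CST3 reversed with quantile normalization (log2 fold change −2.63) and with a floor of 1 (−4.36), where its other probe set became the brighter. Over its alternatives the adjusted p of CST3 ran from 0.00467 to 0.729, that of CCN2 from 0.0357 to 0.427, that of ACTN2 from 0.0427 to 0.666 and that of RPLP2 from 0.0427 to 0.427. The lists for oxidative phosphorylation (medians from −0.55 to −0.25, adjusted p from 2.39e-05 to 0.0118) and ribosomal proteins (−0.44 to −0.21, 5.65e-07 to 0.0118) were called in all 17 alternatives to the values. With an estimated correlation 0 lists were called, with unchanged medians of −0.32 and −0.23 and adjusted p of 0.255 and 0.364. The numbers in the titles do not pair the arrays by any label, and deviations of equal numbers had r = 0.0119 across genes. With the number as a replicate block 1 gene was called, CST3, and 226 had an unadjusted p under 0.05. Where no reason is given, the cause was not tested. Among other named genes and lists, 1831 gene values and 252 list values stayed on their side, 39 and 44 moved, and 7 gene values came past the threshold. The side of a gene was the sign of its log2 fold change. That of a list was the direction given by camera, which can differ from the sign of its median. CST3 lost it in 6 alternatives, 4 of them in its own direction and the 2 reversed ones. The filter at the 75th percentile of brightness left CST3 untested, so the 0 genes called there are not a loss of its call. The 34.7% to 39.9% of probe sets below 0 limit what can be said of dim genes.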

Other observations

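The tests of the cardiomyocyte share, of the other probe sets and of the splits for genes below 0 were chosen after the results were seen.

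The lower oxidative phosphorylation and ribosomal lists were weighed against 2 technical readings. Bright genes had lower fold changes, with a median of −0.11 in the brightest of 10 equal bins, against 0.36 in a dim one, and both lists are bright. Against 10000 random lists matched on brightness the medians lay at the 0.01 percentile for oxidative phosphorylation, the smallest these lists can give, and at the 0.03 percentile for ribosomal proteins, which argues against brightness as the whole cause. At the preset correlation the calls did not rest solely on the array that stood apart. Without failing 2a both lists had a camera adjusted p of 0.0118, the highest of their 17 alternatives. With an estimated correlation neither was called with that array (adjusted p = 0.255 and 0.364) or without it (0.954 for both). The mean of the oxidative phosphorylation list lay below the control range on failing 2a alone. ATP5F1D, with floored control values, raised that mean on every failing array, so it does not show that the fall rests on failing 2a. A smaller share of cardiomyocytes in the failing pools may lower oxidative phosphorylation genes and should lower sarcomere genes alike. The sarcomere median exceeded the oxidative phosphorylation median by 0.66, with a bootstrap 95% interval from −0.11 to 1.11. That interval resamples list members, not arrays. Per array the sarcomere median was 0.51, 0.32 and 0.46 on failing 1a, 1b and 2a, above both control arrays (0.16 and −0.16). A fall was thus not seen in that median, but 6 of its 17 members lay below 0 and the interval holds 0, so this stays open. RNA quality and heart failure itself also stay open and were not tested. The GAPDH ratio differed between the groups, while the actin ratio overlapped and its mean went the other way. The actin ratio was between 0.087 and 0.205 on all arrays, with control means of 4653 at the 3′ and 46876 at the 5′ probe set. Loss of 5′ signal in degraded RNA would not give so low a ratio. With human probe sets on dog RNA it is a poor gauge of RNA quality, and it does not argue against a difference in quality.

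Cystatin C and 11 other genes read below the floor of 20 on both control arrays and above it on all 3 failing arrays. Among the 12 were ATP5F1D, CHRNB1, PER1, RNASEK, TIMP3 and TRIM63. If single probe sets shift through their mismatch signal, other probe sets of these genes need not follow. Only 3 had another probe set, of which 2 (66.7%) went higher, and 3 are too few to decide, since the smallest exact one-sided binomial p they allow is 0.125, so the explanation stays open. Of the 10 splits of the arrays into 2 and 3, only the real one (1) gave as many, 12 against at most 6 in the others, and 10 splits are too few for a share under 0.05.

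The 152 genes at an unadjusted p under 0.05 were likewise more than in any of the other 9 splits, of which the highest, failing 1a and 1b against the rest, gave 82. At the adjusted threshold that split called 2 genes and the real split 1. At an unadjusted p under 0.05 only the real split (1 of 10) gave as many, and 10 splits are too few for a share under 0.05.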
